A study of Homo sapiens with 6 samples.

How the data were processed

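RNA was sequenced from HT1080, an established human fibrosarcoma cell line, in 3 wild-type (WT) libraries and 3 libraries from cells in which GPR56 (approved symbol ADGRG1), an adhesion G protein-coupled receptor, had been knocked out with CRISPR-Cas9. Per the labels' protocols, RNA was purified with a Qiagen column kit and libraries were made with a SMARTER mRNA-Seq kit. The sample descriptions carry the name of the solvent DMSO for both genotypes, and no dose or time is given with it. The labels do not say whether the 3 samples of a genotype were separate cultures or how many knockout clones they came from, so p-values measure the spread between these samples, which may be technical. A difference between genotypes is also a difference between the cell populations that were sampled.

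The authors deposited 1 table of FPKM values, read numbers scaled by gene length and library size, for 58735 genes in the 6 libraries, with each gene's symbol, position, strand, length and biotype. The aligner, the counting tool and its strand setting are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The identifiers, starts and ends of 58735 of 58735 genes nevertheless equal those of the human GENCODE release 29 on GRCh38, so positions are given on GRCh38. Symbols equalled that release for 58708 genes; the remaining ones read as calendar dates in the file.

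The deposited FPKM values multiplied by gene length stepped in whole reads: 100.0% of the values above 0 in every library lay within 0.02 of a whole read. The recovered totals were 16410352 to 16461752 reads in WT and 16955111 to 17276269 reads in the knockout. The library sizes by which the deposited values were divided differed from median-ratio factors computed on the recovered reads by ratios of 0.9972 to 1.0032, and the values were used as deposited. At this depth 1 read in a gene of 1 kb corresponded to 0.0581 to 0.0602 FPKM. Counting intervals and limits derived from reads cover counting error only. Within genotypes, pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 4.92 to 16.5, against 40.78 to 60.41 between genotypes, over genes with a mean of at least 10 reads in the pair). No library was therefore a copy of another, and n counts 3 libraries per genotype. Repeat preparations of 1 RNA could differ in this way too, so the values do not show separate cultures.

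FPKM are not counts, so the test was limma (version 3.58.1 in R 4.3.3; lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1) for the 12000 genes with a mean FPKM of at least 1 over the 6 libraries, with all 6 libraries, genotype as the only term and no block. Tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Fold changes are knockout minus WT on the log2(FPKM + 1) scale, which understates changes of low genes; ratios of mean FPKM are given without the pseudocount. Of 40 gene lists fixed before the data were examined, 36 had at least 5 tested members; 1 of these is not reported here. These were tested with limma's camera (preset correlation 0.01), again with an estimated correlation, and with fry. P-values were adjusted over the lists. Member counts are given over all genes tested and adjusted over the list alone. Lists share members, SLC7A11 being in several. Medians per chromosome and per 20 Mb window with at least 20 tested genes were computed with no test. Intervals of medians come from 2000 bootstrap draws over genes, which are not independent replicates. Exact permutation tests of 3 against 3 libraries cannot give a two-sided p below 0.1.

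Named genes were fixed by rule: ADGRG1; the 8 protein-coding genes with the largest increase and the 8 with the largest decrease among those past the threshold, with a mean FPKM of at least 5 in the higher genotype and no overlap between genotypes; up to 4 members per list with the smallest adjusted p among those past the threshold; and GPX4, SLC7A11, ACSL4, AIFM2, TFRC, CD36, COL3A1, TGM2, LPCAT3, PTGS2 and CHAC1 whatever their values. This gave 149 genes, of which the text names a part. Exons of 61 of them overlap another annotated gene. For 6 (ACTA2, CCNE2, DDIT3, KRT18, LPCAT3 and TAGLN) the overlap on the opposite strand covers at least 10% of the exonic bases and the partner reaches at least 10% of the gene's own mean FPKM. Without a stated strand setting the reads of such pairs cannot be assigned with certainty. HSPA1A and HSPA1B are near-identical copies, and histone genes, mitochondrial genes with nuclear copies and ribosomal protein genes with pseudogenes share sequence too.

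Before use, the test was checked on simulated reads for 11960 genes, a small part of them with known changes: of the changed genes, 59.1% were recovered at 1.5-fold, 85.9% at 2-fold and 96.4% at 4-fold, 5.1% of calls were false, and data without changes gave 0 calls. On the same reads limma-voom, kept as an alternative, recovered 87.9%, 90.6% and 96.4%, with 1.2% of calls false. The simulated genes were drawn independently and without a trend on GC content. These rates therefore do not cover libraries in which such a trend runs with genotype, as it did here. The 15 other settings fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, eBayes without trend, robust eBayes, the replicate number as a block, each library left out in turn, and limma-voom on the recovered reads. Another 4, chosen after seeing the data, were scaling to the column total, scaling to the total without mitochondrial-encoded genes, a correction for GC content and length (in each library a smooth trend of the deviation from the gene's mean on transcript GC content and on log gene length is removed; GC values were found for 99.9% of tested genes), and protein-coding genes only. Other scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Other cell lines and ligand treatments were not analysed here.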

Results

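Libraries of messenger RNA from HT1080 fibrosarcoma cells were compared, 3 from WT cells and 3 from GPR56 knockout (KO) cells. The series concerns GPR56 as a sensor of the steroid 17α-hydroxypregnenolone and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The question put to these libraries was which mRNA levels differ when GPR56 is lost. Between 16410352 and 17276269 reads per library were recovered from the deposited FPKM values. The first principal component held 68.2% of the variance and separated the genotypes.

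ADGRG1, the gene that encodes GPR56 (ENSG00000205336, plus strand of chromosome 16, positions 57610652 to 57665580 on GRCh38), was lower in all 3 KO libraries. Its level was 6.61, 6.07 and 6.87 FPKM in the WT libraries and 2.68, 2.54 and 2.58 FPKM in the KO libraries, from 875 to 989 reads and 371 to 398 reads per library. The mean fell from 6.52 ± 0.41 to 2.60 ± 0.07 FPKM (SD, n = 3 each), a KO to WT ratio of 0.399, with a log2 fold change of −1.06 (SE 0.07, limma adjusted p = 6.24e-05). The mRNA was reduced and still detected in every KO library. The labels do not state where the gene was targeted, and a frameshift need not lower an mRNA.

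The cystine import system and several genes of lipid peroxide control were lower in KO cells. SLC7A11, the cystine/glutamate exchanger subunit whose cystine supply feeds glutathione synthesis, fell from 12.6 ± 1.2 to 1.89 ± 0.27 FPKM (SD, n = 3), 6.67-fold lower (ENSG00000151012, chromosome 4, from position 138164097; log2 fold change −2.24, limma adjusted p = 1.54e-05). Its partner SLC3A2 fell from 60.4 ± 4.1 to 25.7 ± 0.9 FPKM. AIFM2, also called FSP1, which regenerates the radical-trapping form of coenzyme Q, fell from 7.18 ± 1.04 to 2.53 ± 0.24 FPKM (adjusted p = 0.000223). TXNRD1, a thioredoxin reductase, fell from 160.8 ± 8.3 to 84.7 ± 3.5 FPKM.
GPX4, the peroxidase that reduces lipid hydroperoxides, was at 63.5 ± 5.3 FPKM in WT and 75.9 ± 1.4 FPKM in KO (log2 fold change 0.26, adjusted p = 0.025). This call did not hold after correction for GC content and length (log2 fold change 0.04, adjusted p = 0.63) or when any 1 library other than WT 3 was left out (adjusted p of 0.0565 to 0.103). Of the 25 tested genes of ferroptosis defence, 5 were higher, 9 were lower and 11 did not pass (5 and 11 adjusted over the list alone). Camera did not separate the list from the other genes in the main analysis (adjusted p = 0.0821), and called it lower under quantile normalization (0.0439), without KO 3 (0.0389) and after the GC and length correction (0.0433). Here and below, where no second count is given, the counts adjusted over the list alone were the same.

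Genes used as markers of a ferroptotic response were lower as well. Of 9 tested, 6 fell, 1 rose and 2 did not pass (7 lower and 1 higher adjusted over the list alone), with a median log2 fold change of −0.81. Camera called the list lower (adjusted p = 0.0125), a call that was lost with an estimated correlation (adjusted p = 0.24) and with the filter at a mean FPKM of 5 (adjusted p = 0.0582). CHAC1, a glutathione-degrading enzyme, fell from 5.46 ± 0.92 to 0.78 ± 0.43 FPKM. TFRC, the transferrin receptor, fell from 53.9 ± 3.7 to 27.4 ± 1.6 FPKM (adjusted p = 0.000155). HMOX1, which releases iron from heme, fell from 39.0 ± 2.5 to 20.2 ± 0.9 FPKM, and ACSL4, which loads polyunsaturated fatty acids into phospholipid precursors, from 24.6 ± 2.9 to 13.6 ± 0.7 FPKM (adjusted p = 0.000654). DDIT4 was the member that rose, from 16.4 ± 1.4 to 47.1 ± 2.8 FPKM. PTGS2 lay under the expression filter, at 0.67 ± 0.11 and 0.40 ± 0.06 FPKM, and was not tested.

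**Figure D1:**
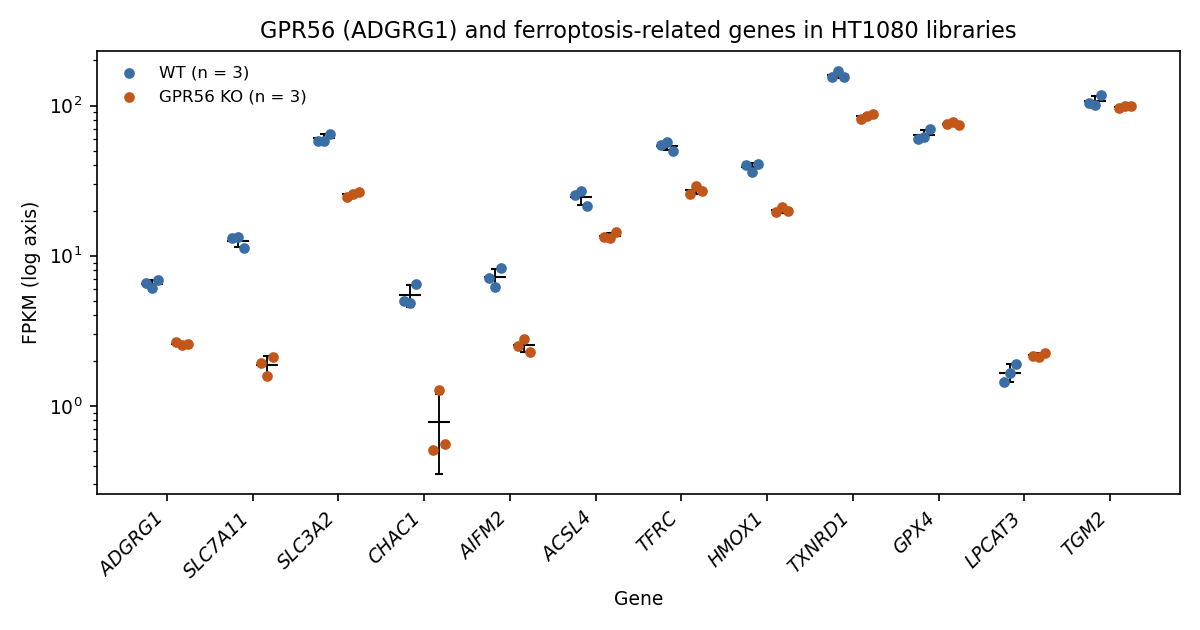
Expression of ADGRG1 and 11 ferroptosis-related genes in FPKM on a log axis; each point is 1 library (WT blue, KO orange), with the mean and SD of 3 libraries in black. SLC7A11 lies between 11.2 and 13.4 FPKM in WT and at or below 2.1 FPKM in KO, whereas the genotypes lie close together for GPX4, LPCAT3 and TGM2.

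Genes that promote ferroptosis were not separated from the other genes. Of 19 tested, 2 were higher and 5 lower, and camera did not call the list (adjusted p = 0.267), while fry, which asks only whether a list moves, gave it as lower (adjusted p = 0.00684). Its median was −0.09, and 0.03 after the GC and length correction. In the list of fatty acid uptake and polyunsaturated fatty acid handling, 5 of 18 were higher and 5 lower (7 and 5 adjusted over the list alone; adjusted p = 0.855). FABP5, a fatty acid carrier, fell from 8.44 ± 0.45 to 1.94 ± 0.30 FPKM, LPCAT1 from 35.2 ± 2.1 to 14.8 ± 0.3 FPKM, and SLC27A1 rose from 2.09 ± 0.27 to 4.33 ± 0.44 FPKM. LPCAT3, which inserts polyunsaturated chains into phospholipids, was at 1.66 ± 0.23 FPKM in WT and 2.17 ± 0.07 FPKM in KO (adjusted p = 0.0528). Of its exonic bases 65.6% overlap EMG1 on the opposite strand, which had a mean of 14.6 FPKM. TGM2, a transglutaminase known to bind the extracellular part of GPR56, was at 107.6 ± 8.8 and 97.9 ± 1.8 FPKM (adjusted p = 0.184; 0.00782 and a log2 fold change of −0.24 after the GC and length correction). CD36, a fatty acid receptor, had 4 reads over the WT libraries and 0 over the KO libraries, and COL3A1, a collagen known as a GPR56 ligand, had 2 and 1 reads, so neither could be compared. Ether lipid and peroxisome genes (3 higher and 3 lower of 20, adjusted p = 0.855; 6 and 2 after the GC and length correction, adjusted p = 0.22) and iron handling genes (5 higher and 4 lower of 22, adjusted p = 0.777) were not called.

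Over all 12000 tested genes, 5207 differed between KO and WT, 2525 higher and 2682 lower in KO (limma, adjusted p under the threshold of 0.05; 6214 genes had an unadjusted p under 0.05). Most of these differences were small on the scale with a pseudocount of 1: 70.4% of the called genes changed by less than 1.5-fold, and 377 changed by at least 2-fold, 204 higher and 173 lower (693 with a pseudocount of 0.1 and 740 with limma-voom on recovered reads). The largest increases under the rule for named genes were in SULF2, PAEP, MMP9, LAPTM5, TMEM132D, PMEPA1, ANGPTL2 and C1orf94. SULF2, a sulfatase that edits heparan sulfate (ENSG00000196562, chromosome 20, from position 47656348), rose from 0.62 ± 0.03 to 23.1 ± 1.1 FPKM, 37.3-fold. PAEP, a secreted lipocalin, rose from 2.90 ± 0.44 to 33.1 ± 5.0 FPKM. The gelatinase gene MMP9 rose from 10.4 ± 0.2 to 79.1 ± 3.5 FPKM and the TGF-beta-responsive gene PMEPA1 from 13.2 ± 0.4 to 82.3 ± 1.8 FPKM. The largest decreases were in IFI44, ACTL8, CCL5, FLNC, CDCP1, ARMCX2, MMP1 and IFIT3. The interferon-inducible IFI44 (ENSG00000137965, chromosome 1, from position 78649796) fell from 40.8 ± 3.4 to 0.93 ± 0.04 FPKM, 43.6-fold, and the chemokine gene CCL5 from 18.4 ± 0.8 to 0.40 ± 0.05 FPKM, 45.8-fold. ACTL8 fell from 97.7 ± 7.0 to 4.32 ± 0.59 FPKM, the actin crosslinker gene FLNC from 17.9 ± 1.8 to 0.46 ± 0.10 FPKM and the collagenase gene MMP1 from 17.7 ± 2.3 to 1.48 ± 0.46 FPKM. The adjusted p of these 16 genes lay between 2.88e-07 and 2.98e-05. The libraries also differed in a GC trend that ran with genotype: across genes, the Spearman correlation of a library's deviation from the gene mean with GC content was −0.40, −0.62 and −0.01 in WT and 0.46, 0.44 and 0.23 in KO, genes not being independent replicates. With that trend and the weaker length trend removed, 3813 of the 5207 genes remained called in the same direction and 4 were called in the opposite one. The corrected values gave 5256 called genes in all, so other genes entered as these were lost.

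Camera called 11 of the 36 lists, and none held with an estimated correlation, where the smallest adjusted p was 0.0743. By fry, which does not compare a list with other genes, 29 lists moved on balance in 1 direction and 36 held changes in either direction.

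Interferon-stimulated genes, which restrict viral replication, were lower in KO, with a median of −0.82 (−0.53 with no filter and −2.14 with the filter at a mean FPKM of 5). Of 23 tested, 15 fell, 0 rose and 8 did not pass (camera adjusted p = 2.61e-08; adjusted p = 0.0743 with an estimated correlation). Besides IFI44 and IFIT3, OASL fell from 10.9 ± 0.9 to 1.01 ± 0.14 FPKM and IFIT2 from 10.9 ± 1.0 to 0.85 ± 0.14 FPKM. In the list of NF-kB targets and cytokines, 4 of 18 rose and 9 fell, without a call (adjusted p = 0.163). TNFAIP2 fell from 8.26 ± 0.62 to 0.27 ± 0.06 FPKM and TNFAIP3 from 6.63 ± 0.50 to 2.10 ± 0.32 FPKM, while CCL2 rose from 5.03 ± 0.78 to 16.2 ± 2.8 FPKM. Antigen presentation genes had 4 higher and 4 lower of 12 (adjusted p = 0.812; 2 higher and 6 lower after the GC and length correction, adjusted p = 0.143), with B2M lower (125.0 ± 9.4 to 75.6 ± 4.3 FPKM) and TAP1 higher (9.16 ± 1.40 to 14.9 ± 0.8 FPKM).

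Targets of p53, which arrests or removes damaged cells, were higher in KO. Of 21 tested, 17 rose, 0 fell and 4 did not pass (median 0.74; camera adjusted p = 8.27e-08; adjusted p = 0.119 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose from 62.1 ± 7.6 to 142.0 ± 2.0 FPKM. BTG2 rose from 4.81 ± 0.14 to 15.2 ± 0.4 FPKM, DDB2 from 14.3 ± 0.3 to 34.8 ± 1.1 FPKM and FDXR from 7.50 ± 0.77 to 23.0 ± 1.1 FPKM. SPATA18, a member under the filter that was singled out after its values were seen, had 146 reads over the WT libraries and 0 over the KO libraries. Of 27 cell cycle genes, 1 rose and 9 fell (median −0.11; camera adjusted p = 0.104; called lower with no filter at 0.0119, under quantile normalization at 0.0211 and after the GC and length correction at 0.00348). CDK1 fell from 26.9 ± 3.9 to 14.1 ± 1.7 FPKM and TOP2A from 67.2 ± 6.3 to 46.6 ± 1.9 FPKM. Replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail, had 3 lower and 0 higher of 7 (adjusted p = 0.102; 0.0433 after that correction).

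Chaperone and stress genes of the endoplasmic reticulum were lower. In the unfolded protein response list 16 of 18 fell, 0 rose and 2 did not pass (17 lower adjusted over the list alone), with a median of −0.71 (camera adjusted p = 1.16e-07; adjusted p = 0.0743 with an estimated correlation). HSPA5, the main chaperone of the compartment, fell from 593.4 ± 17.7 to 232.2 ± 11.4 FPKM and HSP90B1 from 381.4 ± 29.8 to 160.2 ± 8.5 FPKM. DDIT3 fell from 9.46 ± 0.40 to 2.37 ± 0.32 FPKM; 27.2% of its exonic bases overlap MARS on the opposite strand. HERPUD1, at 31.5 ± 3.3 and 9.57 ± 0.57 FPKM, lies on the long arm of chromosome 16, whose tested genes had a median of −0.28. Of 23 targets of ATF4, the transcription factor of the amino acid response, 15 fell, 3 rose and 5 did not pass (17 and 3 adjusted over the list alone; median −0.58; camera adjusted p = 4.9e-05; adjusted p = 0.285 with an estimated correlation). SLC7A5, an importer of large neutral amino acids on the same arm of chromosome 16, fell from 184.7 ± 21.1 to 60.2 ± 1.8 FPKM. Of 13 heat shock genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00242; adjusted p = 0.24 with an estimated correlation). HSPA1A fell from 13.7 ± 1.2 to 3.96 ± 0.18 FPKM, and HSPB8 was the member that rose, from 2.77 ± 0.41 to 7.38 ± 0.62 FPKM. Of 22 targets of NRF2, the regulator of antioxidant genes, 10 fell and 3 rose (camera adjusted p = 0.00797; adjusted p = 0.24 with an estimated correlation). NQO1, again on the long arm of chromosome 16, fell from 54.5 ± 1.8 to 32.9 ± 1.8 FPKM.

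Camera called the lists of glycolysis, nuclear respiratory and ribosomal protein genes higher, with medians of 0.21 to 0.24. In the hypoxia and glycolysis list 13 of 24 rose, 0 fell and 11 did not pass (14 higher adjusted over the list alone; median 0.24; camera adjusted p = 7.66e-05; adjusted p = 0.335 with an estimated correlation). ALDOC, a brain-type aldolase, rose from 3.72 ± 0.35 to 18.8 ± 1.3 FPKM and PFKFB4 from 7.77 ± 0.47 to 20.5 ± 1.2 FPKM. Of 29 nuclear genes of oxidative phosphorylation 12 rose and 0 fell (11 adjusted over the list alone; median 0.24, and 0.18 after the GC and length correction; camera adjusted p = 0.00242; adjusted p = 0.286 with an estimated correlation). UQCRC1 rose from 77.8 ± 4.8 to 127.5 ± 2.1 FPKM. Of 32 ribosomal protein genes 16 rose and 0 fell (18 adjusted over the list alone; median 0.21, and 0.16 after that correction; camera adjusted p = 7.66e-05; adjusted p = 0.341 with an estimated correlation). The call was lost under quantile normalization (median 0.09, adjusted p = 0.0972). RPS19 rose from 282.3 ± 13.2 to 391.6 ± 5.8 FPKM.
Of 13 mitochondrial-encoded genes 4 rose and 0 fell (2 adjusted over the list alone; camera adjusted p = 0.0431; adjusted p = 0.486 with an estimated correlation). This call was lost under quantile normalization (median 0.03, adjusted p = 0.83), with a pseudocount of 0.1 (adjusted p = 0.0524) and without WT 1, WT 3 or KO 2 (adjusted p of 0.0908, 0.0549 and 0.103). Their share of reads was 2.45 ± 0.23% in WT and 3.31 ± 0.46% in KO (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

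Sterol and steroid lists were not called in the main analysis. Of 24 cholesterol biosynthesis genes 11 were higher and 4 lower (camera adjusted p = 0.15; 0.0375, called higher, with no filter). SREBF2 rose from 54.2 ± 2.3 to 75.4 ± 1.5 FPKM and STARD4 fell from 10.8 ± 1.0 to 6.54 ± 0.56 FPKM. Fatty acid synthesis had 4 higher and 2 lower of 14 (adjusted p = 0.24). Steroid hormone synthesis had 2 higher and 0 lower of 11 (adjusted p = 0.38), FDXR and HSD3B7 (1.37 ± 0.10 to 2.48 ± 0.06 FPKM). Most of the 31 members of this list lay under the filter and were not tested. Among these, AKR1C1 had 390 reads over the WT libraries and 14 over the KO libraries, HSD17B2 50 and 2, and AKR1C2 45 and 9. In the other direction, CYP11A1 had 8 and 47 reads and HSD17B1 207 and 311.

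Signalling and matrix lists connected with GPR56 held changes in both directions, and camera called none of them in the main analysis. Of 13 other adhesion G protein-coupled receptors 6 were higher and 2 lower (adjusted p = 0.139), ADGRE1 rising from 0.44 ± 0.05 to 3.12 ± 0.16 FPKM. Ligands and partners of GPR56 had 4 higher and 3 lower of 12 (5 and 4 adjusted over the list alone; adjusted p = 0.972), with the tetraspanin gene CD9 at 1.21 ± 0.04 and 4.10 ± 0.21 FPKM. YAP/TAZ targets had 3 higher and 8 lower of 22 (3 and 9 adjusted over the list alone; adjusted p = 0.0748; 0.0118 with no filter, 0.049 with the filter at a mean FPKM of 5 and 0.00804 after the correction), CYR61 falling from 168.3 ± 4.9 to 97.2 ± 0.6 FPKM. SRF/MRTF targets had 2 higher and 6 lower of 21 (2 and 5 adjusted over the list alone; median −0.05, adjusted p = 0.446; after the correction 3 higher and 13 lower, median −0.18, adjusted p = 0.0433). Immediate early genes had 7 higher and 8 lower of 18 (adjusted p = 0.777), with MYC falling from 27.1 ± 2.3 to 9.42 ± 0.01 FPKM and KLF4 rising from 1.37 ± 0.23 to 5.55 ± 0.18 FPKM.
Collagens and matrix genes had 12 higher and 7 lower of 25 (12 and 8 adjusted over the list alone; adjusted p = 0.208), SPARC rising from 182.5 ± 3.2 to 278.4 ± 15.8 FPKM. Matrix proteases and inhibitors had 7 higher and 6 lower of 18 (adjusted p = 0.282; 0.0288, called higher, with the filter at a mean FPKM of 5), TIMP3 rising from 3.47 ± 0.18 to 10.3 ± 0.3 FPKM. Integrins and cell adhesion had 3 higher and 9 lower of 19 (4 and 9 adjusted over the list alone; adjusted p = 0.231), ITGB3 falling from 1.92 ± 0.22 to 0.35 ± 0.03 FPKM. TGF-beta targets had 6 higher and 5 lower of 16 (adjusted p = 0.304), TGFBI rising from 8.38 ± 0.61 to 22.6 ± 1.1 FPKM. Mesenchymal markers had 3 higher and 3 lower of 11 (adjusted p = 0.777), FN1 rising from 54.8 ± 3.5 to 80.8 ± 2.6 FPKM. Lysosome and endocytosis genes had 7 higher and 5 lower of 36 (6 and 4 adjusted over the list alone; adjusted p = 0.521). The median and the mean or test direction differed in sign for the ether lipid, mesenchymal, and GPR56 ligand lists, and the medians of the ferroptosis promotion, iron handling, matrix protease and TGF-beta lists changed sign after the correction.

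Markers of other cell types were mostly under the expression filter. No hepatocyte marker reached a mean of 1 FPKM, and the highest mean in that list was 0.35 FPKM. Of the epithelial markers 3 were tested and 2 were higher, KRT8 (35.4 ± 2.2 to 55.9 ± 0.7 FPKM) and KRT18, whose call was lost after the GC and length correction (adjusted p = 0.103). Of the endothelial markers TIE1 fell from 13.2 ± 1.4 to 7.33 ± 0.50 FPKM and EGFL7 rose from 8.80 ± 0.81 to 12.2 ± 0.9 FPKM. Of the leukocyte markers LCP1, an actin-bundling protein also found in tumour lines, fell from 108.6 ± 7.9 to 34.7 ± 4.0 FPKM, while CORO1A, at 1.80 ± 0.26 and 2.78 ± 0.20 FPKM, lost its call after that correction (adjusted p = 0.113).

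**Figure D2:**
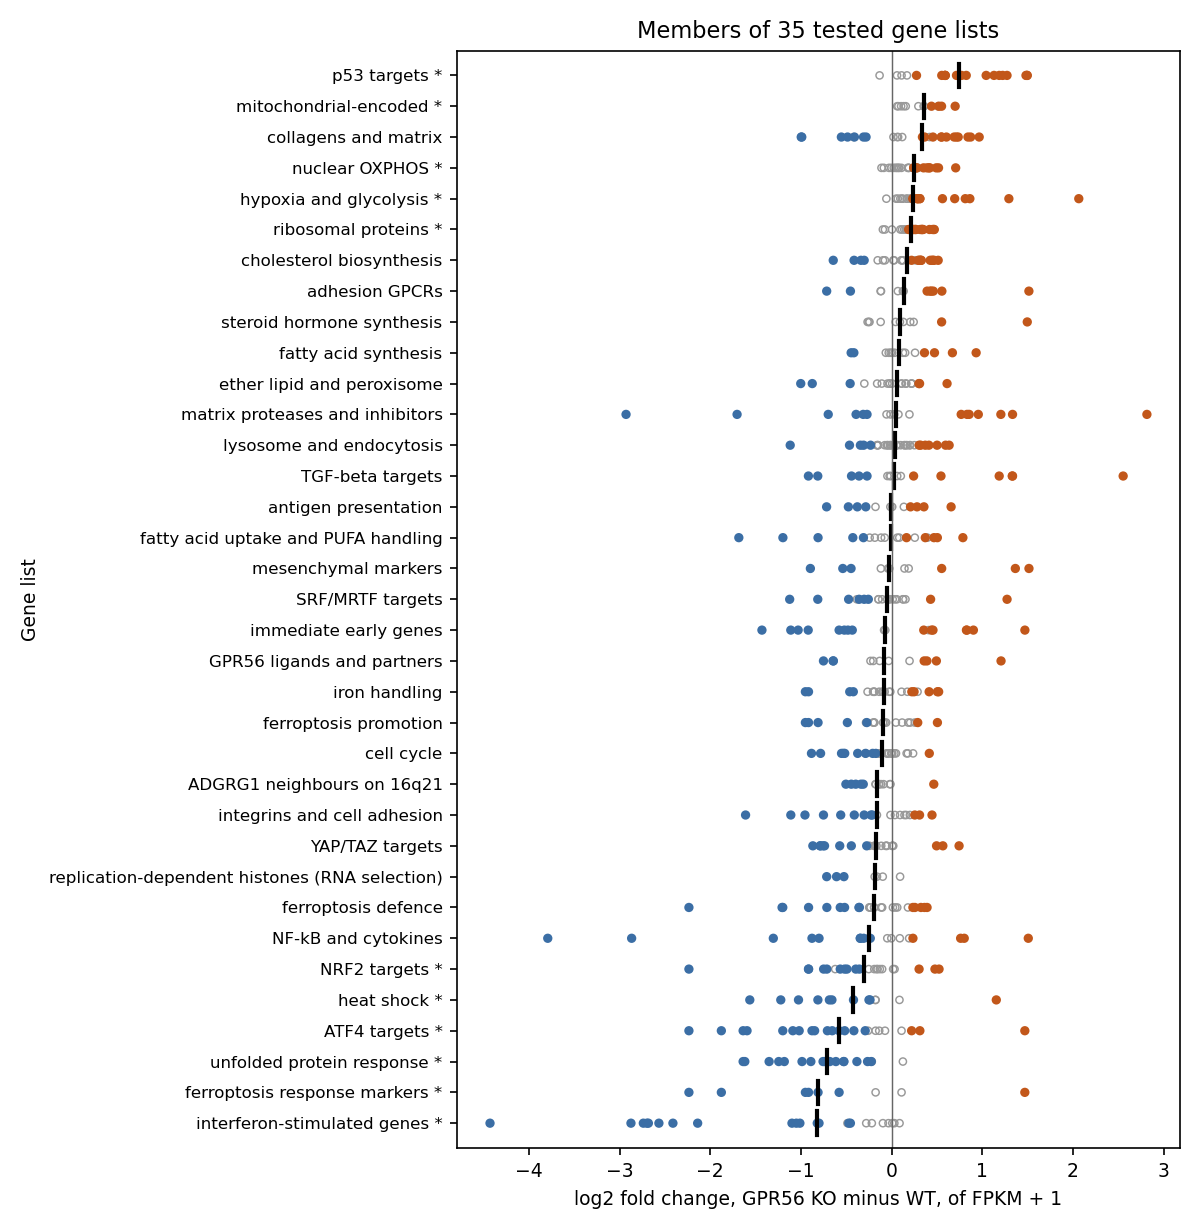
Log2 fold change of FPKM + 1 (KO minus WT) of the tested members of 35 gene lists, sorted by median (black bar); filled points passed the threshold (orange higher, blue lower), open points did not, and an asterisk marks lists called by camera with the preset correlation. The medians run from −0.82 for interferon-stimulated genes to 0.74 for p53 targets.

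Some chromosome regions were shifted as blocks; the long arm of chromosome 16 and the first 50 Mb of chromosome 7 were singled out after their values were seen. On the long arm of chromosome 16, which carries ADGRG1, the 239 other tested genes had a median log2 fold change of −0.28 (95% bootstrap interval −0.33 to −0.22) and 81.6% of them were negative, against a median of 0.04 over the 299 tested genes of the short arm. The 14 tested neighbours of ADGRG1 in 16q21 had 1 higher and 5 lower (camera adjusted p = 0.0767; 0.0126 with the filter at a mean FPKM of 5, 0.0341 without WT 2 and 0.00148, with 10 lower, after the GC and length correction), among them CSNK2A2 (16.9 ± 0.2 to 12.6 ± 0.3 FPKM). Chromosome 13 had the highest chromosome median, 0.22 over 239 genes with 72.0% positive (0.37 after the correction), and the 190 genes in the first 50 Mb of chromosome 7 had a median of 0.30, against −0.02 over the rest of that chromosome. Chromosome 19 had a median of 0.19 (0.04 after the correction), and chromosomes 4 and 18 had the lowest medians, −0.15 each (−0.05 and −0.04 after the correction). Over 153 windows of 20 Mb, medians ranged from −0.39 to 0.42 with an SD of 0.15. The lowest window, 60 to 80 Mb of chromosome 9 (30 genes), stayed at −0.25 after the correction. The window beside it, 80 to 100 Mb (65 genes), was at −0.19 before and −0.16 after the correction.

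**Figure D3:**
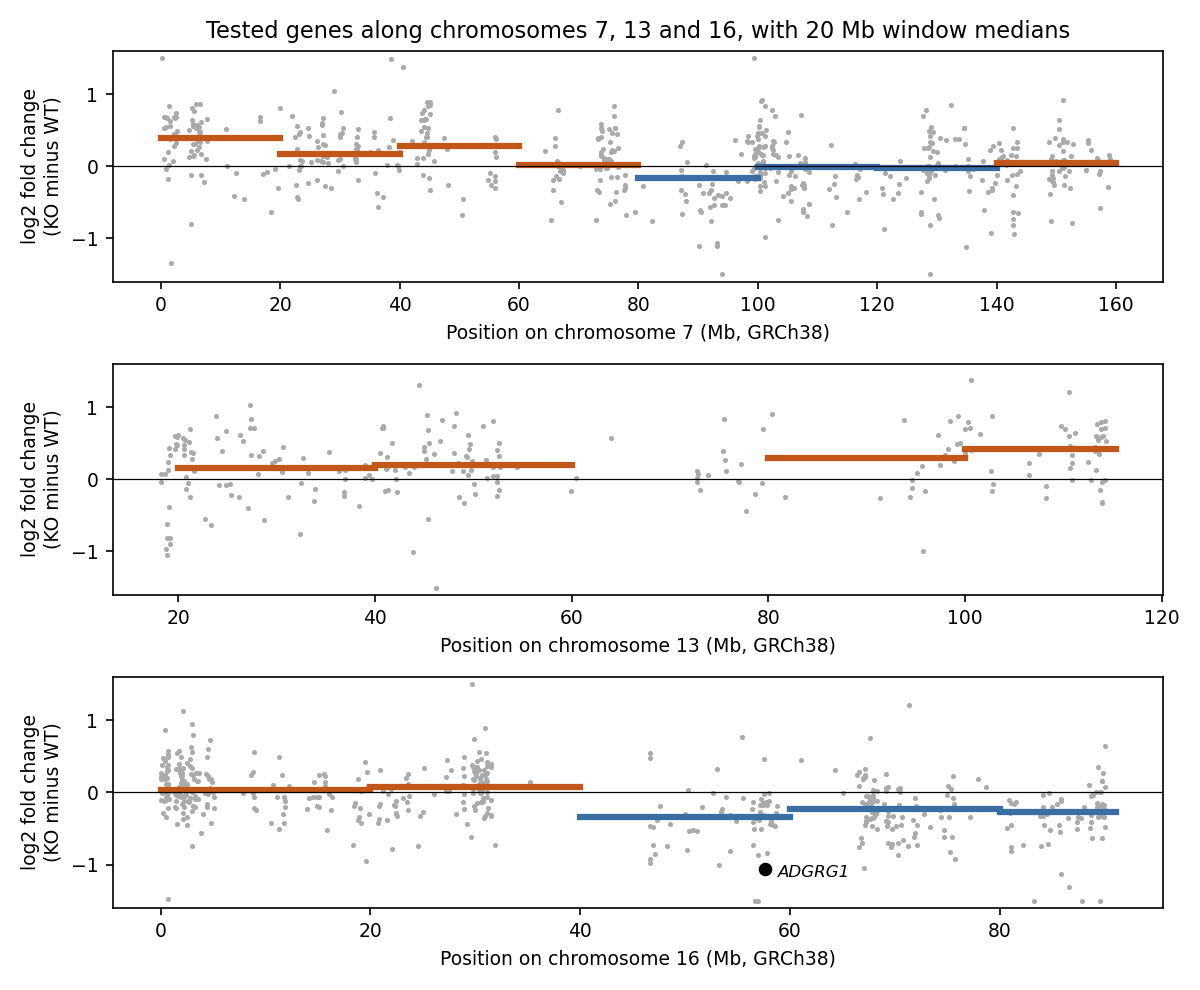
Log2 fold change (KO minus WT, vertical axis, drawn within ±1.5) of each tested gene against its position in Mb on chromosomes 7, 13 and 16; bars are medians of 20 Mb windows with at least 20 genes, orange above 0 and blue below. On chromosome 16 the windows beyond 40 Mb lie between −0.34 and −0.22, and ADGRG1 lies at −1.06.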

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

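The 4 alternatives chosen after seeing the data were scaling to the column total, scaling to the total without mitochondrial-encoded genes, the GC and length correction, and protein-coding genes only; the other 15 were fixed beforehand. No called list or named gene turned direction under any of them. ADGRG1 passed under every alternative that tested it, with log2 fold changes of −1.32 to −1.03 (at a filter of 5 FPKM it is not tested). With the filter at a mean FPKM of 5, which tests 7053 genes, 3203 differed (1639 higher, 1564 lower) and 163 by at least 2-fold. The count at 2-fold or more was 693 with a pseudocount of 0.1 and 740 with limma-voom on recovered reads. After the GC and length correction camera called 17 lists in place of 11, and 0 with an estimated correlation (smallest adjusted p 0.123). Leaving out 1 library gave 3789 to 5372 genes, 362 to 418 at 2-fold, and 10 to 12 lists. Over all alternatives, named genes kept their side of the threshold 2689 times, lost the call 30 times and gained it 8 times. Lists did so 660, 7 and 16 times. Direction was compared only where a result was called in the main analysis or in the alternative. Results called in neither could change sign and still be counted as kept. The share of higher genes among calls was 43.4% with column totals and 48.5% as deposited. Replicate numbers did not pair the libraries (same-number correlations of deviations −0.07, −0.18 and −0.35, no library correlating best with its own number); with the replicate block 3866 genes were called. Depth limits genes near the filter, where 1 FPKM in a gene of 1 kb is 16.6 to 17.2 reads.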

Other observations

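Outside the fixed lists, the genes of this paragraph were chosen after their values were seen, and no test of them as groups was made except where camera is named. Among 4 tested APOBEC3 cytidine deaminases, a family often induced by interferon, 3 were higher in KO: APOBEC3C rose from 24.9 ± 1.7 to 88.9 ± 6.9 FPKM (SD, n = 3), APOBEC3G from 1.08 ± 0.16 to 8.47 ± 0.35 FPKM and APOBEC3F from 1.27 ± 0.12 to 5.01 ± 0.55 FPKM, while APOBEC3B was at 18.3 ± 0.6 and 17.1 ± 2.0 FPKM (limma adjusted p = 0.386). PMAIP1, a p53-inducible BH3-only gene that was in no fixed list, fell from 53.9 ± 2.7 to 16.1 ± 1.6 FPKM, opposite in direction to the 17 p53 targets that rose, as did SPATA18, a member of that list under the filter (146 reads over the WT libraries, 0 over the KO libraries). The TNF family ligands TNFSF9 (26.5 ± 3.0 to 103.5 ± 1.8 FPKM) and CD70 (26.5 ± 4.7 to 85.0 ± 4.2 FPKM) and the growth factor gene TGFA (8.66 ± 0.45 to 34.1 ± 1.7 FPKM) rose. TNFSF9 and CD70 lie close together on chromosome 19 (from positions 6530999 and 6583183). The 4 APOBEC3 genes lie together on chromosome 22 (positions 38982347 to 39087743). Changes within each of these sets may therefore not be independent. Among 167 families of genes sharing a symbol prefix and at least 8 tested members, camera called CEP (centrosomal proteins, 2 higher and 18 lower of 33, adjusted p = 0.0286), RPL and HSPA (medians of −0.27, 0.20 and −0.42 before and −0.15, 0.13 and −0.29 after the GC and length correction, after which camera was not run on families), each with an adjusted p of 0.97 with an estimated correlation. The RPL prefix had 16 higher and 1 lower of 47. The RPS prefix, with 14 higher and 3 lower of 40, was not called (camera adjusted p = 0.121).

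The tests on the long arm of chromosome 16, on chromosome 7 and on the number of lists kept after the correction were written after those values were seen; the tests on ribosomal and respiratory genes and on chromosomes 4, 13 and 18 were written before. The test on genes near 0 reads was written before for the tested genes and widened after to genes under the filter.

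The shift of stress, p53 and translation lists was weighed against the GC and length trend, which runs with genotype. After the correction 10 of the 10 called lists other than the mitochondrial one stayed called in the same direction at the preset correlation (none with an estimated one, where the smallest adjusted p was 0.123), and the 61 ribosomal and nuclear respiratory genes kept a median of 0.1668 (0.2321 before, 95% bootstrap interval 0.13 to 0.24), which argues against the trend as the whole cause. For chance, 10 splits of 3 against 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes (5207, highest other 0), as many at 2-fold (377, highest other 0) and as many lists (11, highest other 7). Every other split set WT and KO libraries on each side in unequal numbers. Such a split kept part of the genotype difference and mixed the genotypes within a side. Calls in the other splits, or their absence, therefore cannot decide on chance. P53 targets and the unfolded protein response were called in 8 of the 9 other splits, with medians of at most 0.33 and 0.29 in size against 0.74 and −0.71. Ribosomal proteins were called in 5 of the 9 (smallest adjusted p 6.35e-06, against 7.66e-05 in the real one) and mitochondrial-encoded genes in 3 (largest median in size 0.38 against 0.35, smallest adjusted p 8.67e-06 against 0.0431). Loss of GPR56, a difference between clones and a difference in culture density or handling stay open and untested.

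The next pattern is the shift of chromosome regions. The arm 16q stayed at −0.3118 relative to all genes after the correction (interval −0.37 to −0.27) and the first 50 Mb of chromosome 7 at 0.3145. Chromosome 13 moved from 0.23 to 0.3744. For these regions the values argue against the GC trend. Chromosomes 4 and 18 shrank on the same relative scale to −0.0425 and −0.0406, as a GC trend would give. Their shares of negative genes, 67.2% and 67.6%, were taken before the correction and carry that trend, so they cannot decide on a loss along them. A loss confined to the part of 16q from ADGRG1 to the telomere would leave the centromere side unshifted. The 52 tested genes on that side were at −0.3291 (interval −0.44 to −0.25), which argues against such a loss as the only difference on the arm. RNA levels cannot exclude it together with another cause on the centromere side. A candidate explanation, as a hypothesis, is a lower copy number of the whole arm in KO relative to WT cells (81.6% of its genes negative, 3 of 3 windows), and a higher one of chromosome 13 (72.0% positive, 4 of 4 windows with enough genes). A higher copy number of the first 50 Mb of chromosome 7 (80.5% positive) is a hypothesis of the same kind. These shares and window directions were taken before the correction and alone cannot tell copy number from a GC trend. After the correction the window medians were −0.32 to −0.29 on 16q and 0.37 to 0.46 on chromosome 13. They were 0.27 to 0.32 up to 60 Mb of chromosome 7, and 0.02 to 0.06 on chromosome 19. Chromosome 19 had 71.7% positive genes and 3 of 3 windows positive, yet a median of 0.04 after the correction. Expression cannot say which genotype departs from the parent line, and DNA copy number was not analysed here. Part of the difference in ADGRG1 mRNA, and in HERPUD1, SLC7A5, NQO1 and CDH13 on 16q, may then be a matter of dosage, although each fell by more than the arm's median of −0.28. With the genes of 16q, chromosome 13 and the first 50 Mb of chromosome 7 left out, the 11 lists stayed called. The windows from 60 to 100 Mb of chromosome 9, also lower after the correction, were not left out.

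The third pattern is a set of 16 autosomal or X-linked genes, chosen after their values were seen, with at most 3 reads in each KO library and at least 30 in each WT library; 11 genes met the reverse. Of the 16, 11 lay under the expression filter, SPATA18 among them, and 5 were tested: ZNF22 (0 reads over the KO libraries against 463 over the WT libraries), CPNE7 (0 against 452), CXCL11 (1 against 239), CXCL10 (1 against 224) and the lincRNA AC015574.1 (0 against 189). Against a limit of 3 reads over the KO libraries, ZNF22 was at least 157-fold lower and CPNE7 at least 153-fold lower. A deletion of all copies that reached the nearest tested genes would bring these close to 0 too, but the 30 nearest ones not in the set, 23 to 2768 kb away, had a median of −0.0755 (95% bootstrap interval −0.30 to 0.00; −0.0205, −0.48 to 0.11, over the 8 beside the 5 tested genes), 10 called lower and 4 higher, and the lowest was NR2F2 beside AC015574.1 at −0.7965 (adjusted p = 0.000178), which argues against deletions that large. CXCL10 and CXCL11 are interferon-inducible chemokine genes adjacent to each other, so a deletion of this pair, smaller deletions elsewhere and silencing of single genes in a clone stay open and untested. For this pair these are not the only explanations left, since interferon-stimulated genes were lower more widely (15 of 23 tested fell and 0 rose).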
